A study of Mus musculus with 6 samples.

How the data were processed

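Bulk poly(A) RNA was sequenced from mouse optic nerve in 6 libraries, 3 from the control diet and 3 from the obesogenic diet. Per the labels' protocols, RNA was extracted with the NucleoSpin RNA Plus XS kit and libraries were made with the SMART-Seq mRNA kit, both made for small amounts of input. The authors deposited a table of transcript abundances in TPM, a unit that divides each transcript's reads by its length and scales each library to a fixed total. The submitters' processing notes name DRAGEN, STAR 2.7.9a, Subread and featureCounts 2.0.3 without roles. The tool that gave TPM, the genome build and the annotation release are not given in the sources used here, so no coordinates are printed.

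The table held 110028 lines for 109383 transcripts of 35850 genes. A transcript with several Entrez identifiers had several lines, always with the same values, and was counted once (415 transcripts). The listed values summed to between 788456 and 832193 TPM per library, below the total that TPM is scaled to, so part of each library was not analysed here. Gene values are sums over the listed transcripts of a gene and can miss some of its isoforms. Values were used as deposited, without rescaling. TPM keeps no depth, so the sequencing depth is unknown and no counting interval was computed. A value of 0 means only that the transcript was listed at 0.

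Transcripts were summed to genes, and genes with at least 1 TPM in at least 3 of the 6 libraries were kept (14364 genes). Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend, as obesogenic minus control. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Transcripts were tested in the same way. Every adjusted p of a gene or transcript comes from limma and is two-sided. It compares 3 libraries with 3, except where a library is said to be left out. An exact permutation test of a single gene in this design cannot give a p below 0.1, so none was used.

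Gene lists were tested with limma's camera against all other genes tested, with the inter-gene correlation preset at 0.01. Lists needed at least 5 tested genes, and p-values were adjusted over lists. Of 45 lists fixed before the data were examined, 43 could be tested. The same lists were run with the correlation estimated for each list and with fry, a rotation test of the list alone. Within a list, the members' p-values were also adjusted over the list alone. A further 11 lists were written after the data were seen, and are adjusted among themselves.

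The rule for the genes named was also fixed before the data were examined. Per direction it takes the 10 genes with the largest change among those past the threshold whose libraries do not overlap between diets. Where fewer exist, it fills up with non-overlapping genes of smallest unadjusted p with a mean of at least 2 TPM, said not to pass. Gene models without an established symbol, pseudogenes and immunoglobulin or T-cell receptor segments are counted and not named. The rule adds Nf1, Gfap and the sex-linked genes, and up to 4 members of smallest unadjusted p for each list described. Genes named outside the rule are said to have been chosen after their values were seen.

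The fits were tested on simulated data that kept the real genes' means, with 200 of 14364 genes changed. With noise at the spread found within diets, 6.0% of 67 genes changed by 1 log2 unit, 62.7% of 67 changed by 2 and 80.3% of 66 changed by 3 were called, along with 3 unchanged genes. With noise at the spread of the control libraries, the shares were 38.8%, 80.6% and 83.3%, along with 7 unchanged genes. The simulated noise was independent between genes.

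Alternatives covered the pseudocount, the filter, the scaling between libraries, the sample number as a block, array weights, the eBayes settings, protein-coding genes only, the most abundant transcript per gene and the removal of each library in turn. Rescaling without immunoglobulin genes, and leaving out obesogenic libraries 1 and 3 together, were added after seeing the data. A planned covariate, the level of Xist, was not run because the table did not list Xist. Figures were drawn with matplotlib in Python.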

Results

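The series profiled optic nerves of 6-week-old mice that form optic glioma, to ask how exposure to an obesogenic diet affects gene expression in that tissue. The mice carried a floxed Nf1 allele, an Nf1 allele with the R681X mutation, and Cre recombinase driven by the GFAP promoter, which is active in glial cells. Nf1 encodes neurofibromin, a negative regulator of RAS. The control diet was PicoLab 5053. The obesogenic diet was an AIN-76A formula with 58% of its energy from fat, with sucrose, and the series title describes the exposure as maternal. Each diet had 3 libraries. The labels do not say that libraries came from separate animals or litters. The p-values of single genes and transcripts therefore measure the spread between these samples, which may be technical. List p-values from camera with its preset correlation compare a list's genes with all other genes as if genes were nearly independent. These list p-values are no measure of the spread between libraries. Other splits of the libraries into 3 and 3 called between 11 and 24 lists at that setting, and the split by diet called 19. With a maternal exposure, libraries from the same litter would not be independent of each other. TPM values carry no sequencing depth. The number of genes at 1 TPM or more was 14081, 13824 and 14051 in control libraries 1, 2 and 3 and 14514, 14337 and 14449 in obesogenic libraries 1, 2 and 3.

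The median of genes of the meninges, the sheath around the nerve, was lower in every obesogenic library than in any control library. The list of meningeal fibroblast and arachnoid markers fell as a group, with a median log2 change of -1.35 over 17 tested genes (camera, adjusted p = 3.67e-20; adjusted p = 0.26 with an estimated correlation). All 17 members had a lower obesogenic mean, and in 14 the libraries of the diets did not overlap. All 17 passed when adjusted over the list alone, and 0 passed over all genes tested. Aldh1a2, a retinoic acid synthesising enzyme, measured 289 ± 37.5 TPM in control and 98.4 ± 9.2 TPM in obesogenic libraries (SD, n = 3; limma adjusted p = 0.119). Fmod, a collagen-binding proteoglycan, measured 416 ± 75 against 131 ± 18.7 TPM, and Ogn, another small proteoglycan, 258 ± 47.3 against 100.2 ± 13.4 TPM. The extracellular matrix list also fell, with a median of -0.87 over 22 genes (adjusted p = 2.44e-08; adjusted p = 0.54 with an estimated correlation). Of its members, 8 passed when adjusted over the list alone and 0 over all genes. Col1a1 was at 255 ± 65.9 against 80.3 ± 20.5 TPM and Col3a1 at 41.4 ± 12.5 against 9.61 ± 5.08 TPM. Col1a1, Col1a2 and Col3a1 are also members of the meningeal list, so the matrix list is not a separate finding for these genes.

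The 10 genes that the rule names on the lower side were all below their control libraries in every obesogenic library, and none passed the threshold over all genes (adjusted p from 0.0755 to 0.131). Fgfbp1 (ENSMUSG00000048373), a secreted FGF-binding protein, measured 77.5 ± 8.66 TPM in control and 15.8 ± 2.91 TPM in obesogenic libraries, a log2 change of -2.23 (SE 0.21, adjusted p = 0.0755). Wnt6 (ENSMUSG00000033227) had a log2 change of -1.64 (SE 0.17, adjusted p = 0.0848), from 129 ± 11.1 to 40.6 ± 3.04 TPM. Igf2 (ENSMUSG00000048583), an insulin-like growth factor, measured 548 ± 158 against 132 ± 8.55 TPM, and Bmp7 (ENSMUSG00000008999), a bone morphogenetic protein, 177 ± 8.52 against 70.2 ± 6.41 TPM. The betaine and GABA transporter gene Slc6a12 was at 40.9 ± 2.18 against 12.2 ± 1.42 TPM. Ppic, Serpind1 and Mfap5 had log2 changes of -1.45, -1.46 and -1.60, and Aldh1a2 and Fmod of -1.54 and -1.65. Aldh1a2 and Fmod are members of the meningeal list, so they are not a separate finding. Whether the other genes named here follow the lower meningeal transcripts was not tested. Without obesogenic library 2, each of these 10 passed, with adjusted p from 0.0175 for Fgfbp1 to 0.0199 for Igf2. The log2 change of Fgfbp1 was then -2.21 (SE 0.21), no larger than over all libraries. An adjusted p depends on the other genes of the fit, and that fit called 914 genes, 735 of them higher. When any other library was left out, none of these 10 passed.

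Vascular genes followed the same direction. The endothelial list fell by a median of 0.84 on the log2 scale, with 18 of 19 genes lower (adjusted p = 1.7e-11; adjusted p = 0.54 with an estimated correlation). The pericyte and smooth muscle list had a median of -1.11, with 12 of 13 genes lower (adjusted p = 2.44e-08; adjusted p = 0.54 with an estimated correlation). Adjusted over the list alone, 9 endothelial and 4 pericyte genes passed, and 0 of either passed over all genes. Itm2a measured 519 ± 107 against 221 ± 24.4 TPM, and Cdh5, which encodes the endothelial cadherin, 15.0 ± 2.34 against 5.90 ± 0.412 TPM. Vtn, a pericyte marker, measured 763 ± 114 against 338 ± 27.2 TPM. Macrophages of the brain's borders express Cd163 and F13a1, and their list fell with a median of -0.89 over 12 genes (adjusted p = 1.18e-05; adjusted p = 0.26 with an estimated correlation). In that list 5 genes passed when adjusted over the list alone and 0 over all genes. F13a1 was at 29.3 ± 1.51 against 11.2 ± 3.04 TPM. The neutrophil and mast cell list had a median of -1.05 over 11 genes (adjusted p = 2.03e-05; adjusted p = 0.59 with an estimated correlation), with 0 genes past when adjusted over the list alone. S100a8 in it measured 25.1 ± 5.01 against 7.37 ± 5.82 TPM. With obesogenic library 2 as the lone obesogenic library, where the spread comes from the control libraries only, the endothelial and pericyte calls held, and the matrix, border macrophage and neutrophil lists did not pass (adjusted p = 0.105, 0.404 and 0.476). Medians relative to the control mean in obesogenic libraries 1, 2 and 3 were -0.77, -0.995 and -0.66 for the endothelial list and -1.06, -1.10 and -0.70 for the pericyte list, against -1.34, -0.996 and -1.44 for the meningeal list. As deposited, endothelial and pericyte medians were thus lowest in obesogenic library 2, where the meningeal median was least low. Immunoglobulin genes made up 20.8% of the listed TPM of that library, which lowers its other values. These medians were not rescaled for that share, so the rank of obesogenic library 2 in the endothelial and pericyte lists is not settled.

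**Figure D1:**
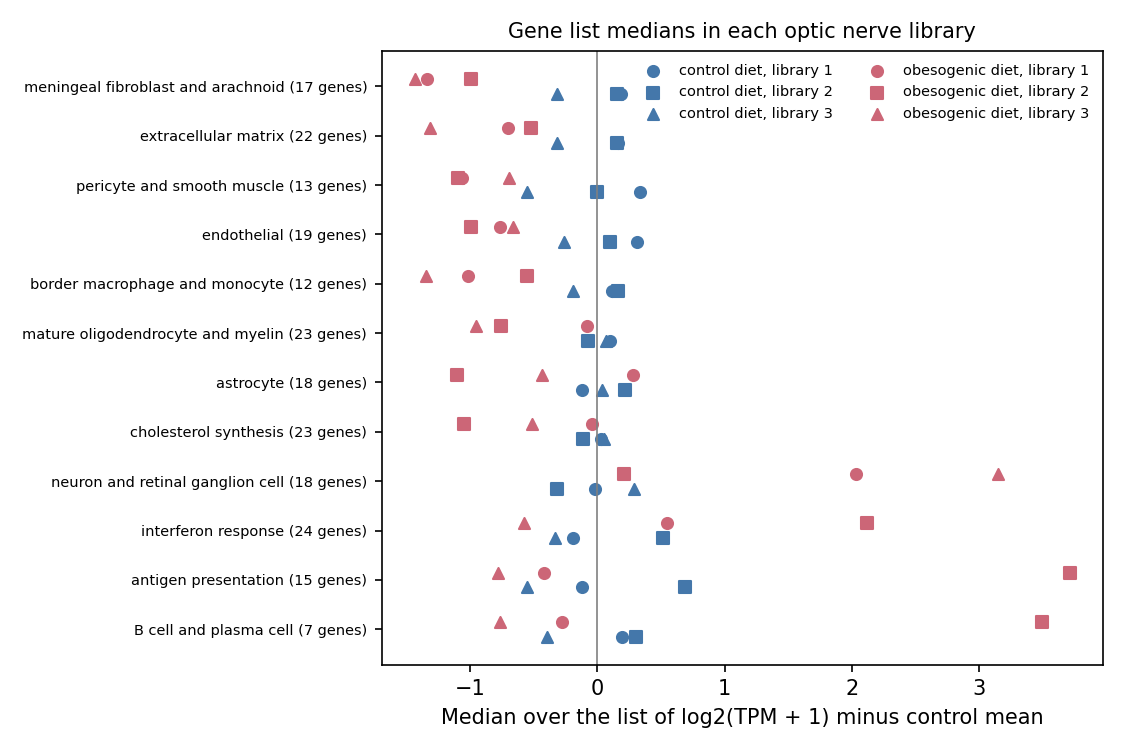
Median of log2(TPM + 1) minus the control mean over the genes of 12 fixed lists (x axis, log2 units) in each library; colours stand for diets and marker shapes for libraries. The meningeal list sits at -1.34, -0.996 and -1.44 in the obesogenic libraries, the neuron list at 2.04, 0.21 and 3.14, and the antigen presentation list at -0.42, 3.71 and -0.78.

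Glial lists had smaller medians and were not low in every obesogenic library. Mature oligodendrocyte and myelin genes had a median of -0.58, with 22 of 23 lower (adjusted p = 1.16e-09; adjusted p = 0.59 with an estimated correlation), and 0 passed when adjusted over the list alone or over all genes. Their medians relative to control were -0.08, -0.76 and -0.95 in obesogenic libraries 1, 2 and 3, and without obesogenic library 1 the list's median was -0.88. Mobp, a myelin protein gene, measured 9664 ± 1744 against 4799 ± 1967 TPM, and Cldn11, the tight junction gene of myelin and arachnoid, 393 ± 74.4 against 182 ± 47.5 TPM. The cholesterol synthesis list had a median of -0.46, with 21 of 23 genes lower (adjusted p = 8.79e-06; adjusted p = 0.60 with an estimated correlation) and 0 past over the list alone. Its library medians were -0.04, -1.05 and -0.52, and its median was -0.70 without obesogenic library 1 and -0.28 without obesogenic library 2. Dhcr7 in it measured 96.4 ± 13.9 against 53.9 ± 15.0 TPM. The astrocyte list had a median of -0.35 (adjusted p = 0.00813; adjusted p = 0.77 with an estimated correlation), with library medians of 0.28, -1.10 and -0.44. It did not pass without control library 2 (adjusted p = 0.0576) or obesogenic library 2 (median -0.17, adjusted p = 0.34), and its median was -0.54 without control library 1 and -0.62 without obesogenic library 1. The oligodendrocyte precursor list had a median of -0.25 (adjusted p = 0.00813; adjusted p = 0.79 with an estimated correlation) and did not pass without control library 3 (adjusted p = 0.202) or obesogenic library 2 (median -0.048, adjusted p = 0.166); without obesogenic library 1 the median was -0.41. In neither list did a gene pass over the list alone.

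Other glial and signalling lists passed with small medians. The reactive astrocyte list was at -0.37 (adjusted p = 0.0247; adjusted p = 0.81 with an estimated correlation), with 1 gene past over the list alone, Hspb1, a small heat shock protein gene at 190 ± 3.84 against 91.0 ± 9.89 TPM. This call was lost without control library 1 (median -0.088, adjusted p = 0.102), control library 2 (adjusted p = 0.0977), obesogenic library 1 (median -0.17, adjusted p = 0.378) or obesogenic library 3 (median -0.020, adjusted p = 0.782). Without obesogenic library 2 the median was -0.76. The precursor glia list was at -0.32 (adjusted p = 0.0417; adjusted p = 0.77 with an estimated correlation), and it was lost without control library 2 (0.0617), control library 3 (0.0583), obesogenic library 2 (0.0936) or obesogenic library 3 (0.166); its median was -0.50 without obesogenic library 1. The list of Wnt, Notch, Hedgehog and TGF-beta targets was at -0.19 (adjusted p = 0.0247; adjusted p = 0.72 with an estimated correlation), and it was lost without control library 3 (0.0726), obesogenic library 2 (0.0692) or obesogenic library 3 (0.132). Its median was -0.077 without control library 1, -0.34 without control library 2, -0.33 without obesogenic library 1 and -0.12 without obesogenic library 3. Id3, a BMP-responsive gene in both of these lists, measured 461 ± 46.7 against 268 ± 59.4 TPM. The retinoid and thyroid hormone list was at -0.32 over 15 genes (adjusted p = 0.000546; adjusted p = 0.60 with an estimated correlation), with 4 genes past over the list alone and 0 over all genes. Its library medians were -0.11, -0.91 and -0.25, and its median was -0.13 without obesogenic library 2, -0.51 without obesogenic library 1 and -0.17 without control library 3. Its leading members were Aldh1a2 and Crabp2, both also genes of the meninges, and Crabp2 measured 193 ± 12 against 64.9 ± 18.1 TPM. The glucocorticoid response list was at -0.39 over 14 genes (adjusted p = 0.00184; adjusted p = 0.60 with an estimated correlation), with Sult1a1 at 110 ± 6.56 against 51.1 ± 7.20 TPM the 1 gene past over the list alone. Its library medians were -0.045, -0.49 and -0.36, and its median was -0.135 without obesogenic library 2 and -0.25 without control library 3.

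For lipid handling, the fatty acid oxidation and PPAR target list fell by a median of 0.19 (adjusted p = 0.00382; adjusted p = 0.59 with an estimated correlation), with 21 of 23 genes lower and 0 past over the list alone. Without obesogenic library 1 its median was -0.35. The list of lipid uptake, droplet and LXR targets did not pass (median -0.14, mean 0.07, adjusted p = 0.555). In it Plin2, a lipid droplet coat protein gene, measured 6.01 ± 1.73 against 19.7 ± 12.5 TPM (adjusted p = 0.343). Fatty acid synthesis did not pass (median -0.20, adjusted p = 0.0507), and it passed without control library 2 (adjusted p = 0.0417) or obesogenic library 1 (adjusted p = 0.000191).

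Neuronal transcripts were higher in obesogenic libraries 1 and 3. The neuron and retinal ganglion cell list rose by a median of 1.82 log2 units, with 17 of 18 genes higher (adjusted p = 1.02e-06; adjusted p = 0.66 with an estimated correlation), and 0 passed over the list alone or over all genes. Its medians relative to control were 2.04, 0.21 and 3.14 in obesogenic libraries 1, 2 and 3, and without obesogenic library 3 its median was 1.08. Snap25, a synaptic vesicle fusion gene, measured 45.9, 10.1 and 90.2 TPM in these libraries, against 4.90 ± 2.82 TPM in control. On the higher side the rule names 10 genes, none past the threshold (adjusted p from 0.119 to 0.176). Npy (ENSMUSG00000029819), the appetite-stimulating neuropeptide Y, measured 2.77, 1.73 and 9.97 TPM in control and 312, 83.1 and 431 TPM in obesogenic libraries, a log2 change of 5.54 (SE 0.72, adjusted p = 0.119). Pomc (ENSMUSG00000020660), the precursor of melanocortin peptides, was at 4.47 ± 2.04 TPM in control and at 332, 35.9 and 547 TPM in obesogenic libraries (log2 change 5.18, SE 0.93, adjusted p = 0.174). Cited1 measured 3.20 ± 1.01 against 69.6 ± 57.7 TPM and Rasgrp1, a RAS activator, 2.44 ± 0.867 against 16.8 ± 4.13 TPM. Fcho1, Cmtr1, Plxnc1, Fhad1, Pitpnm1 and Tmem200a had log2 changes of 1.75, 1.33, 1.81, 2.59, 1.82 and 2.15. Cmtr1, an mRNA cap methyltransferase gene, had similar values in all obesogenic libraries, at 146, 129 and 109 TPM against 50.7 ± 11 TPM in control. Without obesogenic library 2 each of these 10 passed, Pomc with adjusted p = 0.0136 and Tmem200a with adjusted p = 0.043. The fits without control library 1 or 3, or obesogenic library 1 or 3, called 0 genes.

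Obesogenic library 2 stood apart by immune transcripts. Immunoglobulin genes made up 20.8% of its listed TPM, against 0.0044%, 0.045% and 0.0118% in the control libraries and 0.0053% and 0.0046% in obesogenic libraries 1 and 3. Igkc, the kappa light chain constant segment, chosen after its values were seen, was listed at 73060 TPM there and at 97.2 TPM or below elsewhere. The interferon response list rose by a median of 0.72, with 22 of 24 genes higher (adjusted p = 0.00813; adjusted p = 0.81 with an estimated correlation), and 0 passed over the list alone. Its library medians were 0.55, 2.12 and -0.58, and without obesogenic library 2 the median was -0.02 and the list did not pass (adjusted p = 0.173). After rescaling without immunoglobulin genes the list missed the threshold although its median was not smaller (0.83, adjusted p = 0.0824). It also did so without control library 1 (adjusted p = 0.0667) or control library 3 (median 0.47, adjusted p = 0.0578); without obesogenic library 3 its median was 1.37. Antigen presentation genes, such as H2-K1 and Tap1, had library medians of -0.42, 3.71 and -0.78, T and NK cell genes of -0.54, 3.27 and -0.30, and B and plasma cell genes of -0.28, 3.49 and -0.77. None of these lists passed over all libraries (adjusted p = 0.177, 0.2 and 0.577), and without obesogenic library 2 each had a lower median and passed (-0.50, -0.34 and -0.36, with adjusted p = 0.000708, 0.00849 and 0.0233). They passed in the higher direction without obesogenic library 3 (adjusted p = 0.000265, 0.00676 and 0.041). Without obesogenic library 1, antigen presentation and T and NK cell genes did so too (adjusted p = 0.00368 and 0.00168), and antigen presentation without control library 2 (adjusted p = 0.0465).

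**Figure D2:**
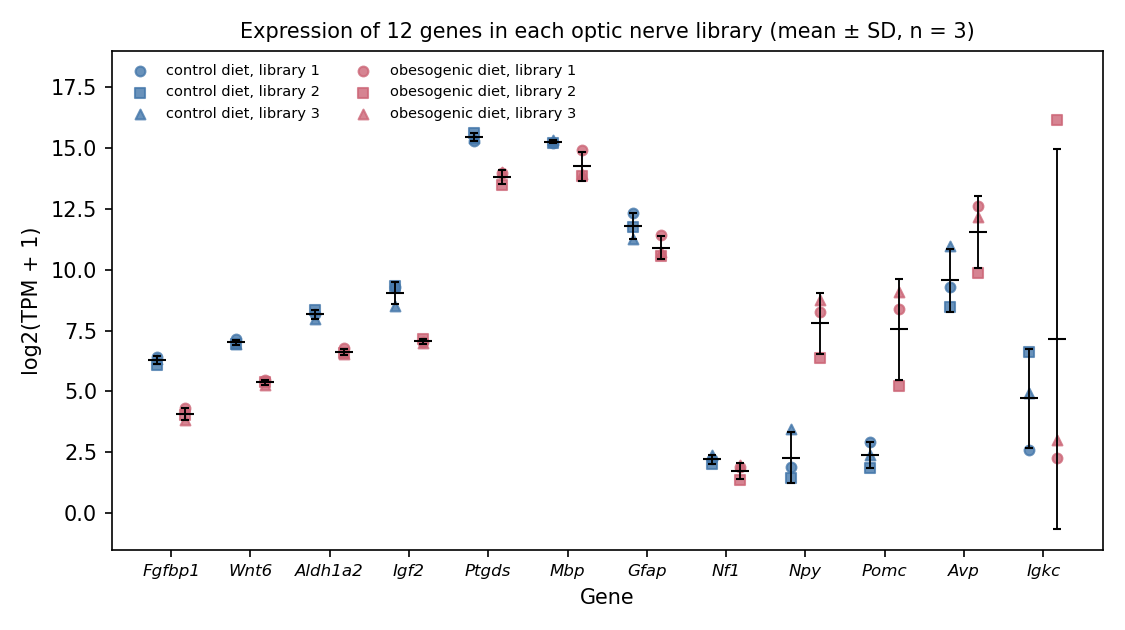
Expression of 12 genes (x axis) as log2(TPM + 1) (y axis) in each library; colours stand for diets, marker shapes for libraries, and black bars for the mean ± SD over 3 libraries. Fgfbp1, Wnt6, Aldh1a2 and Igf2 lie below all control libraries in every obesogenic library, and Igkc at 73060 TPM is far above the others in obesogenic library 2; Ptgds, Mbp, Avp and Igkc were chosen after their values were seen.

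Genes tied to the glioma itself did not pass. Nf1 (ENSMUSG00000020716), summed over its listed transcripts, measured 3.68 ± 0.595 TPM in control and 2.40 ± 0.740 TPM in obesogenic libraries (log2 change -0.48, SE 0.33, adjusted p = 0.647). The genotype was the same in both diets. Gfap (ENSMUSG00000020932), the astrocyte filament gene, measured 3701 ± 1361 against 1996 ± 691 TPM (log2 change -0.88, adjusted p = 0.468). The list of MAPK output genes had a median of -0.05 (adjusted p = 0.188), and passed without control library 1 (median -0.28, adjusted p = 0.016). Phlda1, a MAPK-induced gene, was at 73.7 ± 8.90 against 41.0 ± 9.06 TPM (adjusted p = 0.269). The cell cycle list had a median of 0.42 (adjusted p = 0.325), with -0.01 without obesogenic library 2, and passed without obesogenic library 3 (0.80, adjusted p = 0.012). The list of Nf1 optic glioma stroma genes holds chemokines, chemokine receptors and other genes such as Mdk, Nlgn3, Igf1, Adam10 and Cd44. It had a median of 0.40 (camera, adjusted p = 0.495), with -0.35 without obesogenic library 2. It passed without obesogenic library 3 (0.76, adjusted p = 0.0287). Homeostatic microglia genes had a median of 0.14 while camera pointed lower against the other genes (adjusted p = 0.727), with library medians of -0.22, 1.17 and -0.53, and passed in the lower direction without obesogenic library 2 (-0.43, adjusted p = 6.57e-05).

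Over all 14364 genes, limma called 1 gene between the diets at the adjusted threshold. At unadjusted p under 0.05 there were 1575 genes, 857 higher and 718 lower, where 718 are expected with no difference. In 1276 genes every obesogenic library was above every control library and in 1070 below, together 16.3% of genes against the 10% that chance gives. The gene called, named after its values were seen, was Gm9836 (ENSMUSG00000081071), a processed pseudogene listed at 32.1, 17.9 and 22.1 TPM in control and at 0 in the obesogenic libraries (adjusted p = 0.0204). Reads of such a gene can come from its parent gene, and its call held without obesogenic library 2 and was lost without any of the other 5 libraries. Without obesogenic library 2 the count was 914 genes, 735 higher and 179 lower. It was 0 without control library 1, control library 3, obesogenic library 1 or obesogenic library 3, and 1 without control library 2. Obesogenic library 2 alone against the controls, chosen after seeing the data, gave 193 genes, 121 higher and 72 lower; the spread there comes from the control libraries only, so this count describes 1 library and not the diet. Correlations between libraries across genes were 0.942 to 0.947 within control, 0.812 to 0.937 within the obesogenic diet and 0.858 to 0.925 between diets. Of the 43 lists tested, 19 passed, 17 lower and 2 higher. With an estimated correlation 0 passed (smallest adjusted p = 0.26; 2 lists at unadjusted p under 0.05), and with fry 0 passed (smallest adjusted p = 0.0759; 6 lists at unadjusted p under 0.05). The 24 lists that did not pass had medians from -0.30 to 0.95.

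At the level of single transcripts, 2 of 35408 passed, and 2996 had an unadjusted p under 0.05. The transcript Ctbp1-202 (ENSMUST00000200899), of a transcriptional corepressor gene, was listed at 0 in control and at 44.2, 32.6 and 73.0 TPM in obesogenic libraries (adjusted p = 0.0373). The sum over Ctbp1 transcripts was 220.0 ± 17.1 against 258 ± 68.6 TPM. The other was the single transcript of Gm9836 (adjusted p = 0.0496). The count was 0 without control library 1, 2 or 3 or obesogenic library 1 or 3, and 4 without obesogenic library 2. Of the 20 transcripts with the smallest p, 16 were listed at 0 in all libraries of 1 diet, and an exact 0 can be a failed estimate of an isoform.

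Markers of tissues next to the nerve were low in most libraries. Skeletal muscle genes fell by a median of 0.96 over 7 tested genes (adjusted p = 0.00813; adjusted p = 0.62 with an estimated correlation), a call lost without control library 1 (median -0.56, adjusted p = 0.0849), and 0 passed over the list alone. Des in it measured 7.06 ± 3.94 against 2.47 ± 0.185 TPM, the 1 member whose libraries did not overlap between diets. It is also a member of the pericyte and smooth muscle list, so it does not stand for skeletal muscle alone. The photoreceptor and pigment cell lists had 3 and 2 tested genes and were not tested. The mean log2(TPM + 1) of photoreceptor genes was 0.99, 0.97 and 1.72 in the control and 0.99, 0.86 and 0.89 in the obesogenic libraries. Haemoglobin genes made up 0.959%, 0.958% and 4.34% of listed TPM in control and 1.54%, 3.28% and 0.422% in obesogenic libraries. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y were present in all 6 libraries. Kdm5d measured 10.1 ± 0.745 against 7.73 ± 2.15 TPM (adjusted p = 0.689) and Eif2s3y 51.1 ± 11.2 against 45.6 ± 8.0 TPM (adjusted p = 0.868). Uty and Ddx3y had log2 changes of -0.25 and -0.07 (adjusted p = 0.882 and 0.967).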

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

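Gene counts at the adjusted threshold were 0 with a pseudocount of 5, without a filter and over protein-coding genes only (with 1528, 1795 and 1517 genes at unadjusted p under 0.05), 2064 with array weights (1505 higher, 559 lower) and between 0 and 914 when a library was left out. Array weights gave obesogenic library 2 a weight of 0.19, obesogenic library 3 a weight of 0.45 and obesogenic library 1 a weight of 4.69, and 900 of these genes were also past in the same direction without obesogenic library 2. Without obesogenic libraries 1 and 3, chosen after seeing the data, the count was 193; this leaves 1 obesogenic library, so the spread comes from the control libraries only. Other pseudocounts, filters and scalings gave 1. The count of lists was 0 with an estimated correlation and with fry, and otherwise between 16 and 25, with 12 of the 19 calls kept in each of the 6 fits that left out a library. Transcript counts were 1 with a pseudocount of 0.1 or a filter of 5 TPM, 0 with a pseudocount of 5, without a filter or with the sample number as a block, and 0 to 4 when a library was left out. The cause of these differences was not tested. The planned Xist covariate was not run.

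Sample numbers are shared between the diets in the sample titles, and the title number is the one used here. The submitters' own library names carry other numbers and do not give the same pairing. A block by title number may therefore join unrelated libraries. With the number as a replicate block, 1 gene passed, higher and not the gene called without it, along with 22 lists (3 higher, 19 lower) and 0 transcripts. Deviations of libraries with the same number correlated at 0.008, 0.177 and 0.132 across genes, and not every library correlated best with its own number, since obesogenic library 1 reached 0.107 with control library 3. The numbers were not taken to pair the libraries.

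With an estimated correlation or fry, which keep the medians, all 19 lists lost their call. Their medians were -1.35 for meninges, -0.84 for endothelium, -0.58 for myelin, -0.87 for matrix, -1.11 for pericytes, 1.82 for neurons, -0.46 for cholesterol synthesis, -0.89 for border macrophages, -1.05 for neutrophils, -0.32 for retinoids, -0.39 for glucocorticoids, -0.19 for fatty acid oxidation, -0.96 for muscle, -0.25 for oligodendrocyte precursors, 0.72 for interferon, -0.35 for astrocytes, -0.19 for Wnt and related targets, -0.37 for reactive astrocytes and -0.32 for precursor glia. With fry, homeostatic microglia (0.14) pointed higher. Fatty acid synthesis passed with a pseudocount of 0.1 (-0.20), a filter of 5 TPM (-0.20), no filter (-0.20), median-ratio scaling (-0.25), the replicate block (-0.20) and rescaling without immunoglobulin genes (-0.094). T and NK cells passed without a filter (0.89) and antigen presentation with the block (0.70). Calls lost were reactive astrocytes with median-ratio scaling (-0.39), interferon without immunoglobulin genes (0.83), and, with quantile normalization, astrocytes (-0.41), reactive astrocytes (-0.50) and precursor glia (-0.48).

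Array weights ended the calls of muscle (-0.24), oligodendrocyte precursors (0.074), interferon (0.46), astrocytes (0.096), Wnt targets (-0.013) and precursor glia (-0.047). Homeostatic microglia (-0.23), antigen presentation (-0.40) and T and NK cells (-0.38) passed in the lower direction. Directions turned in that fit for glioma stroma (0.27) and cell cycle (0.074), where the test pointed lower, B and plasma cells (-0.20), antigen presentation (-0.40), T and NK cells (-0.38) and fatty acid synthesis (0.21), and for the genes Uty (0.47), Ddx3y (0.12), Eif2s3y (0.030), Aif1 (-0.13), Trbc2 (-0.28), Cd3d (-0.40), Jchain (-0.023) and Elovl6 (0.063). Ddx3y was at 0.026 after rescaling without immunoglobulin genes. The fit without obesogenic libraries 1 and 3 sets obesogenic library 2 alone against the controls, was chosen after the neuronal and immune values were seen, and describes that library and not the diet. In it calls ended for matrix (-0.53), neurons (0.21), border macrophages (-0.55), neutrophils (-0.63), fatty acid oxidation (-0.40), muscle (-0.96), Wnt targets (-0.52) and precursor glia (-0.44). Glioma stroma (1.39), cell cycle (1.17), B and plasma cells (3.49), antigen presentation (3.71), T and NK cells (3.27) and fatty acid synthesis (-0.86) passed, as did reactive astrocytes (0.71, adjusted p = 9.32e-05) and homeostatic microglia (1.17, adjusted p = 5.06e-08) in the higher direction. For MAPK output the test pointed higher, although the median stayed negative (-0.29, adjusted p = 0.797). Directions turned for Ddx3y (0.70), Olfml3 (0.45) and Nlgn3 (-0.035). The cause of these differences was not tested.

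Leaving out a library gave ranges of -1.06 to -0.56 for skeletal muscle, -0.41 to -0.048 for oligodendrocyte precursors, -0.019 to 1.37 for interferon response, -0.62 to -0.17 for astrocyte, -0.34 to -0.077 for Wnt targets, -0.76 to -0.020 for reactive astrocyte, -0.50 to -0.22 for precursor glia, -0.51 to -0.13 for retinoids, -0.46 to -0.135 for glucocorticoids, -0.35 to 0.76 for glioma stroma, -0.28 to 0.047 for MAPK output, -0.008 to 0.80 for cell cycle, -0.36 to 1.80 for B cell and plasma cell, -0.50 to 1.29 for antigen presentation, -0.34 to 1.61 for T and NK cell, -0.43 to 0.51 for homeostatic microglia and -0.50 to 0.14 for fatty acid synthesis. For genes they were -0.25 to 1.40 for Aif1, -0.31 to 1.75 for Cd79b, -0.46 to 0.46 for Ddx3y, -0.13 to 1.97 for H2-K1, -0.24 to 4.69 for Jchain, -0.29 to 2.23 for Tap1 and -0.29 to 1.93 for Vpreb3. The median change of all genes was 0.079, and -0.035 after quantile normalization, 0.18 with array weights or rescaled without immunoglobulin genes, and -0.16 without obesogenic libraries 1 and 3. Depth is unknown, so no value can be ranked by it.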

Other observations

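The counts over other splits of the libraries were set before those splits were run; the other tests below, and the 11 lists they use, were chosen after the result was seen. The genes named here were also chosen after their values were seen.

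Peptide genes of the hypothalamus had high values in obesogenic libraries 1 and 3, with exceptions. Avp, which encodes vasopressin, was listed at 6257, 933 and 4584 TPM in obesogenic libraries 1, 2 and 3 and at 619, 351 and 2038 TPM in the control libraries. Oxt, for oxytocin, measured 702, 202 and 559 TPM against 156, 50.2 and 130 TPM. Sst, Cartpt and Gal reached 429, 248 and 119 TPM in obesogenic library 3, where their control means were 1.91 ± 2.26, 6.38 ± 2.78 and 6.76 ± 3.79 TPM. Vip was at 204 and 48.4 TPM in obesogenic libraries 1 and 2 but at 4.38 TPM in library 3. Agrp, which arcuate neurons express together with Npy, stayed at 0.401 TPM or below in all 6 libraries. Without obesogenic library 2, Sst, Pomc, Npy, Hcrt and Tac1 had the largest changes among the genes past the threshold that have an established symbol, with log2 changes of 6.58, 6.36, 6.25, 5.16 and 5.03.

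Among the added lists, the hypothalamic neuron list rose by a median of 2.24 over 21 genes (camera, adjusted p = 7.73e-10; adjusted p = 0.4 with an estimated correlation) and the synapse and vesicle list by 1.87 over 33 genes (adjusted p = 1.08e-14; adjusted p = 0.4 with an estimated correlation). The hypothalamic list was not rerun without genes seen beforehand, so its test adds no support. The tanycyte and ependyma list rose by 0.73 (adjusted p = 0.0117; adjusted p = 0.4 with an estimated correlation) and the pituitary list by 2.11 (adjusted p = 0.00838; adjusted p = 0.46 with an estimated correlation), with control library 1 also 2.18 above the control mean in the latter. Lists of cortical and hippocampal, striatal and cerebellar neurons had medians of 0.48, 0.64 and 1.02 and did not pass (adjusted p = 0.273, 0.288 and 0.0788). Without obesogenic library 2 the striatal and cerebellar lists passed (medians 1.38 and 1.63, adjusted p = 0.0497 and 0.0167) and the cortical list did not (0.285, adjusted p = 0.654). Plasma cell, lymph node and gland lists had medians of 0.64, 0.49 and 0.16 and did not pass (adjusted p = 0.273, 0.589 and 0.994). In obesogenic library 2 alone the plasma cell list stood at 1.80 and the lymph node and follicle list at 2.40, of whose listed genes 9 were tested. In the latter Cxcl13 was at 754 TPM there, but Glycam1, a gene of lymph node vessels, was at 0.263 TPM against 2.89, 1.30 and 2.08 TPM in control libraries, and Ccl21a, a lymph node stromal chemokine, at 0.923 TPM. Without that library their medians were -0.24 and -0.435, and the lymph node list passed in the lower direction (adjusted p = 0.0151; adjusted p = 0.0731 for plasma cells). Leptomeningeal genes beyond the fixed list had a median of -1.31 over 25 genes, but 7 of these had been seen to be lower before the list was written and 6 are also in a fixed list, so its test adds no support. The 14 tested genes outside both sets had a median of -1.095, with 13 lower and 10 below all control libraries in every obesogenic library (adjusted p = 1.63e-13; adjusted p = 0.118 with an estimated correlation). The synapse list also held 2 genes seen beforehand, and 26 of the 27 tested genes outside these and the fixed lists lay above all control libraries in obesogenic libraries 1 and 3. Ptgds, a prostaglandin synthase gene abundant in arachnoid cells, measured 45280 ± 5336 TPM in control and 14680 ± 2789 TPM in obesogenic libraries. Genes listed at 0 in all libraries of 1 diet and above 1 TPM in all of the other numbered 10, and other splits of the libraries gave between 4 and 13. The same count for transcripts was 222, against 141 to 216 for other splits.

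The first pattern is the set of neuronal and neuropeptide transcripts in obesogenic libraries 1 and 3. In obesogenic library 2 the hypothalamic list also stood above the highest control library. The values were 0.82 against 0.156 over tested genes and 0.30 against 0.11 over all listed genes. More neuropeptide RNA per neuron with no more neuronal RNA is argued against as the whole cause, since the synapse list's lower median in obesogenic libraries 1 and 3 was 2.24 and the highest control library stood at 0.23. The fixed neuron list already stood at 2.04 and 3.14 there, so the synapse list is no separate test of this. Hypothalamic brain tissue carried with the nerve is a candidate explanation: 32 of 33 synapse-list genes, 28 of which average at least 1 TPM in control libraries and 4 of which are in a fixed list, lay above all control libraries in both obesogenic libraries 1 and 3. This count restates the higher neuronal transcripts and by itself points to no brain region. The hypothalamic list, of whose 21 tested genes 13 average at least 1 TPM in control libraries, exceeded the cortical list of 6 tested genes by 2.45 and 3.24 log2 units there, by 2.45 and 2.28 over genes at 1 TPM or more in control, and by 1.92 and 2.32 over all listed genes. The hypothalamic list was written after the result was seen and was not rerun without genes seen beforehand. Its excess can therefore follow in part from how the list was chosen. Striatal, cerebellar and pituitary lists also lay above the control mean, at 1.04, 1.01 and 2.86 in library 1 and 0.87, 2.24 and 2.95 in library 3 (0.97, 0.40 and 0.92, and 1.17, 0.42 and 0.96, over all listed genes), so the source tissue is not settled. An effect of the diet on neurons or axons in or near the nerve was not tested and stays open, since the diet and any difference in dissection run together.

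The second pattern is the immunoglobulin share of obesogenic library 2. Plasma cells in the tissue of that library are a candidate source, since 10 of the 11 tested plasma-cell genes other than Jchain were above all 5 other libraries there; Jchain measured 2215 TPM and Mzb1 201 TPM. All 12 tested genes of that list, Jchain included, average at least 1 TPM in control libraries, and 2 are also in a fixed list; Mzb1 was too low elsewhere to be tested. The lymph node and follicle list stood higher there than the plasma cell list over tested genes but lower over all listed genes, at 1.35 against 2.40, so lymphoid tissue was neither shown nor excluded. The share taken from the TPM total is argued against as the whole cause of the lower glial transcripts in that library. Computed over the listed TPM, which sum to less than that total, the share gives a shift of -0.34. On rescaling without immunoglobulin genes the myelin list's median there went from -0.76 to -0.47. The lowest control value was then -0.07 and the control SD 0.09. Whether the cells came with inflammation of the nerve, with other tissue or from another sample was not tested.

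The third pattern is the set of meningeal transcripts lower in all obesogenic libraries. Dilution of the whole nerve by other RNA cannot be told apart from a loss of meningeal RNA in any of them. In obesogenic library 1 the meningeal median lay -1.26 from the myelin median, with control differences of 0.09, 0.23 and -0.38 (SD 0.32), but brain RNA carries myelin transcripts, so myelin is no reference in a library with raised neuronal transcripts. In obesogenic libraries 2 and 3 the differences were -0.24 and -0.48, both within 2 SD of the control mean of -0.019, although the latter is below each control difference. The same limit holds there, since the synapse list stood at 0.27 and 3.15, above the highest control library at 0.23. The comparison with myelin therefore decides nothing in any obesogenic library. Less meningeal sheath in the obesogenic dissections and an effect of the diet on the sheath cannot be told apart either: the 17 of 17 genes lower are the observation itself and test neither.

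There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split called 1 gene and the highest other split 2, with 6 of the 10 splits calling as many as the real one. At unadjusted p under 0.05 the real split had 1575 genes and the others 281 to 1654, the highest with control libraries 1 and 2 and obesogenic library 2 on one side. For lists the real split called 19 and the highest other 24, with 7 of 10 splits calling as many. For transcripts the real split called 2 and the highest other 19, with 4 of 10 calling as many. That highest split put control library 1 with obesogenic libraries 1 and 3 against the rest, and called 2 genes and 22 lists. A transcript count several times the real one may point to some structure of the libraries, but neither that nor its nature was tested. Principal components, the axes of largest variance, were taken over the 500 most variable genes. The first (47.4%) put obesogenic libraries 1, 2 and 3 at 25.73, -37.12 and 43.25. Control libraries 1, 2 and 3 lay between these, at -5.87, -20.13 and -5.86. On the second (29.4%) all control libraries were at -15.38 or below and all obesogenic libraries at 6.73 or above.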
